A study of Mus musculus with 6 samples.

How the data were processed

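The series holds 6 one-channel Agilent mouse expression arrays, 1 per mouse, of macrophages differentiated from C57BL/6 bone marrow for 5 days at 37 °C and 5% CO2 in medium with 10% fetal bovine serum and 10 ng/mL GM-CSF, per the labels' protocols. The labels give 3 independent mice of each of 2 genotypes, all 11 weeks old, with 2 males and 1 female in each, so the mice are biological replicates. Total RNA was amplified and labelled with a cyanine dye, per the labels' protocols. Replicate numbers are not shared between genotypes, so nothing pairs the mice.

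The scanner files hold spot intensity values that the authors extracted with Agilent Feature Extraction, version 10.7.3.1 per the file headers and 9.1 per the submitters' processing notes. The processed signal in the deposited files is an intensity that was background-subtracted and spatially detrended within each array, per the file headers, with no scaling between arrays. Each array has 62976 spots, of which 59305 are not controls, for 55681 probes. Probes were designed on mm9 per the file headers. No gene symbols stand in the columns used, so probes were named through their transcript accession and a table of RefSeq genes (assembly GRCm38.p6), which was used for names and for which genes neighbour each other. Of 55681 probes, 26413 matched a symbol (20018 symbols) and 29268 had none here, 613 of them with a RefSeq transcript accession. A deposited table of the whole series gives log2 values of 3215 probes. Set against the scanner values, each of its columns correlated with its own array at 0.999 or above, and each probe had been centred on its median over the 6 arrays. The column medians were 0.14, 0.11 and 0.11 for WT 1, 2 and 3 and -0.10, -0.13 and -0.13 for KO 947, 948 and 949, and how the authors scaled the arrays before that is not given in the sources used here. In all 3215 probes, 3 of them control probes, the 2 genotypes did not overlap (1447 higher and 1768 lower in KO), so the table holds probes that separate the groups and is no independent evidence of a difference. It served as an alternative only.

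For the main analysis, the log2 processed signal of each spot was reduced by the log2 of the 75th percentile of its array, spots marked as outliers (0.20% to 0.39% of spots) were left out, and spots of 1 probe were averaged. Probes had to be well above background on at least 3 of the 6 arrays whatever the group. For genes with several such probes, the probe with the highest mean was used, which left 15736 genes, 35 of them with 1 missing value. The lowest log2 level well above background ran from -6.16 to -5.68 over the arrays. Where no probe of a gene was well above background on any array of a group, the fold is a bound. It is the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of that lowest level and the measured value, on the log2 scale.

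Genotypes were compared with limma 3.58.1 (lmFit and eBayes without a trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No covariate was used. The slide was left out since with it KO 947 alone sets the contrast, and the value with the slide as a block therefore equals the one within the slide that holds both genotypes. Sex was tested as female minus male with genotype as covariate, and as an interaction. A set of 31 gene lists was tested with camera at a preset correlation of 0.01, with adjustment over the lists. The test, lists, alternatives and rule for named genes were fixed before the data were examined. That rule took Bach1 and its listed targets, the 12 largest rises and falls past the threshold with groups that do not overlap, up to 4 members per list past the threshold or 2 as values where none passed, the sex-linked genes and the neighbours of Bach1 past the threshold. Names that are only identifiers were counted and not named.

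The fit was tested on simulated data for the comparison of KO with WT. Values were drawn for 15701 genes from the real means and spreads, with 200 genes changed. It called 31 of 67 genes changed 2-fold (46.3%), 56 of 67 changed 4-fold (83.6%) and 61 of 66 changed 8-fold (92.4%), and 4 unchanged genes.

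Alternatives were quantile normalization, scaling to the array median, normexp background correction (offset 50) with quantile normalization, no filter or a filter on all 6 arrays, the slide as a fixed or random block or the 1 slide with both genotypes, sex as a covariate, arrays labelled male only, the mean of a gene's probes or every probe on its own, outlier spots kept, eBayes with trend and robust, array weights, each array left out, the authors' table, camera with an estimated correlation, fry, no covariate in the sex test and a threshold of 0.1. Normexp had been planned on mean spot signals and was run on the median spot signals that the files hold. Leaving out the marker lists of other cell types was added after seeing the data. Probes without a symbol were tested apart from the genes.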

Results

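Messenger RNA was profiled in macrophages grown from mouse bone marrow with granulocyte-macrophage colony-stimulating factor (GM-CSF), to compare wild-type (WT) mice with mice lacking Bach1, a heme-binding transcriptional repressor. Each genotype was represented by 3 independent mice of 11 weeks, of which 2 were labelled male and 1 female, and each mouse gave 1 array. The WT mice are called WT 1, 2 and 3, and the Bach1 knockout (KO) mice KO 947, 948 and 949, after their labels. WT 1, 2 and 3 and KO 947 lay on 1 slide, and KO 948 and 949 on another. The share of spots well above background was 70.5%, 70.3% and 73.2% on the WT arrays and 64.5%, 65.1% and 62.5% on KO 947, 948 and 949, so every KO array lay below every WT array. No spot was saturated. Levels are given as log2 signal relative to the 75th percentile of the array, and differences as KO minus WT. The number of arrays, 3 per genotype, limits the precision of every value.

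The first comparison asked how the absence of Bach1 was reflected in Bach1 itself and in genes of heme and iron handling that it is known to repress. The single Bach1 probe read 2.21, 2.48 and 2.59 in WT 1, 2 and 3 and 1.45, 2.00 and 2.23 in KO 947, 948 and 949, a log2 difference of -0.54 ± 0.24 (SE, n = 3 mice per genotype) that did not pass the test (adjusted p = 0.262; -0.98 with the slide as a block, adjusted p = 0.126). Where this probe lies relative to the deleted part of the gene is not given in the sources used here, so it does not check the genotype labels. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 4.40-fold in KO macrophages (log2 difference 2.14 ± 0.25, SE, n = 3 per genotype, adjusted p = 0.0114), from 5.30 ± 0.46 to 7.44 ± 0.10 (mean ± SD), and all KO arrays lay above all WT arrays. A second Hmox1 probe also rose, by 3.82 on the log2 scale, more than the first, so the 2 probes differ on the size of the rise. Slc40a1, which encodes the iron exporter ferroportin, rose 3.33-fold (1.74 ± 0.27, adjusted p = 0.0280), from 4.68 ± 0.52 to 6.41 ± 0.11. These were the 2 of 16 measured genes of the fixed Bach1 target list that passed the limma test, and also the 2 that passed when adjusted over the list alone. The other 14 targets did not pass. They included the ferritin subunits Fth1 (-0.04 ± 0.21, adjusted p = 0.932) and Ftl1 (-0.13 ± 0.17, adjusted p = 0.718) and the glutathione synthesis genes Gclm (0.72 ± 0.38, adjusted p = 0.345) and Gclc (-0.62 ± 0.34, adjusted p = 0.361). The log2 differences of the remaining 10 ran from -0.38 for Txnrd1 and Nqo1 to 0.39 for the heme transporter Slc48a1, with Mafg at 0.21 (-0.08 with the slide as a block), Fech at 0.18, Slc7a11 at 0.06, Me1 and Sqstm1 at -0.27, Blvrb at -0.29 and Srxn1 at -0.34. The list as a whole was not shifted against other genes (camera adjusted p = 0.744), with a median of -0.09 (-0.12 with the slide as a block), a mean of 0.17 and a test direction upward. Leaving out 1 array gave medians from -0.24 (without WT 3) to 0.02 (without WT 2), and the list passed in none of these fits.

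**Figure D1:**
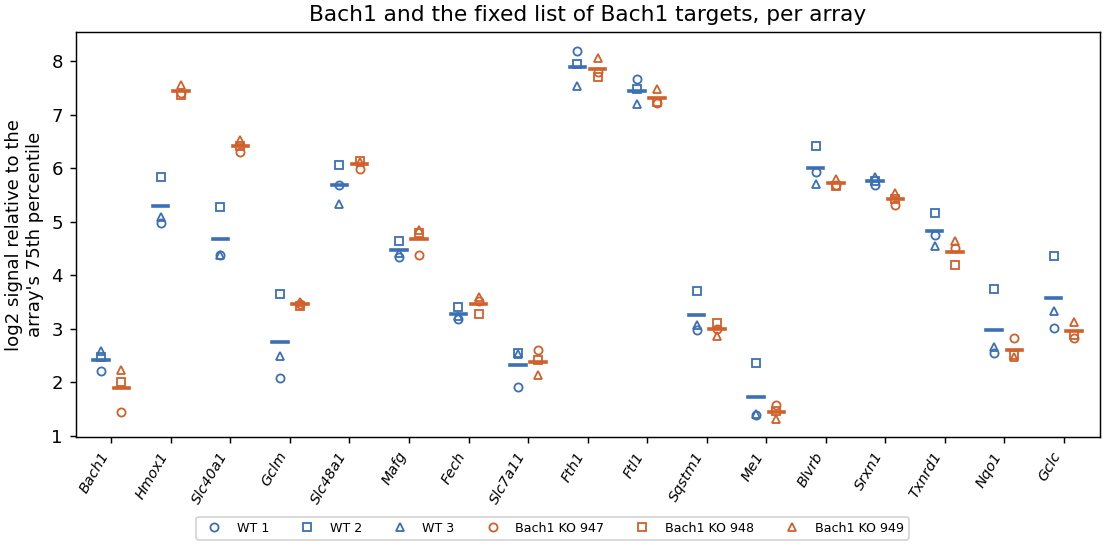
Levels of Bach1 and its listed targets on each array (y axis, log2 signal relative to the 75th percentile of the array), with open symbols for the 3 WT (blue) and 3 KO (orange) arrays and bars for the group means. Hmox1 and Slc40a1 separate the genotypes, with means of 5.30 and 4.68 in WT against 7.44 and 6.41 in KO.

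Beyond the targets, the list of iron and heme handling genes held 30 measured members, of which Hmox1 and Slc40a1 rose, Heph fell and 27 did not pass (2 rises and 1 fall adjusted over the list alone). Heph, which encodes the ferroxidase hephaestin, fell by 1.72 ± 0.22 on the log2 scale (adjusted p = 0.0153), and with the slide as a block its difference was -1.33 and no longer passed (adjusted p = 0.0702). None of the 13 heme synthesis genes passed, and none had an unadjusted p under 0.05. Cpox, which encodes coproporphyrinogen oxidase, had a difference of 0.38 (-0.37 with the slide as a block). With the slide as a block, Hmox1 kept a difference of 2.10 (adjusted p = 0.0739) and Slc40a1 of 1.62 (adjusted p = 0.139), which no longer passed. The call of Hmox1 was also lost without WT 1 (adjusted p = 0.0518), that of Slc40a1 without WT 1, WT 3, KO 948 or KO 949 (adjusted p = 0.102, 0.0731, 0.0932 and 0.0823) and that of Heph without WT 1, WT 2 or KO 948, with the direction kept each time. As the genotypes did not overlap in these 3 genes, leaving out an array could not reverse a direction. All 3 calls were lost on arrays labelled male only (adjusted p = 0.0813, 0.148 and 0.0992). That of Slc40a1 was also lost with the slide as a random block (adjusted p = 0.0524) and with no filter on dim probes (adjusted p = 0.0502).

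Across the transcriptome, the KO cultures had more Arg1, Spic and Ccl7 transcript and less Ccn2, Sparc and Col1a2 transcript than the WT cultures. Of 15736 genes tested with limma, 537 changed at an adjusted p under 0.05, with 180 higher and 357 lower in KO, and 419 of them changed at least 2-fold (113 higher, 306 lower). In all 537 the 3 KO arrays lay on 1 side of the 3 WT arrays, as they did in 26.9% of all tested genes against the 10% that chance gives. The largest rise was that of Arg1, the arginase that splits arginine into ornithine and urea, from -5.09 ± 0.94 in WT to 1.25 ± 0.59 in KO (6.34 ± 0.51, adjusted p = 0.0093), although only 2 of the 3 WT arrays were well above background. Rnf183 rose by 4.28 ± 0.38 and Arnt2, a partner of basic helix-loop-helix PAS factors, by 4.04 ± 0.51, with 1 and 2 WT arrays above background. Spic, a transcription factor of iron-recycling macrophages, rose 9.26-fold (3.21 ± 0.38, adjusted p = 0.0122) from -0.08 ± 0.78 to 3.13 ± 0.20. Further large rises were in Bmp2 (2.95 ± 0.46), Ms4a8a (2.72 ± 0.38), Zbtb7c (2.46 ± 0.27, 1 WT array above background), Zcchc24 (2.44 ± 0.25), the lectin Fcna (2.34 ± 0.26), the lipopolysaccharide-binding protein gene Lbp (2.29 ± 0.21) and the monocyte chemoattractant Ccl7 (2.21 ± 0.23).

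The largest fall was that of Ccn2. This gene, which encodes connective tissue growth factor, was at least 271-fold lower in KO, where no array was well above background (WT mean 2.13 ± 1.46, adjusted p = 0.0093). Sparc fell by 7.84 ± 0.66 on the log2 scale, with both of its probes lower, and the type I collagen genes Col1a1 and Col1a2 fell by 5.62 ± 0.77 and 5.55 ± 0.49. Serpinh1, the collagen chaperone, fell by 6.06 ± 0.76. WT 3 was the lowest WT array for Ccn2 (0.44 against 2.94 and 3.00 on WT 1 and 2), Sparc (1.31 against 3.78 and 3.79), Serpinh1 (-0.90 against 1.96 and 1.88), Col1a1 (-1.99 against 1.01 and 0.70) and Col1a2 (0.64 against 2.58 and 2.35). The sizes of these falls depend on it. Not well above background on any KO array, and so given as bounds, were Prss23 (at least 19.7-fold lower), the basophil protease gene Mcpt8 (at least 19.98-fold, with WT levels of -2.53, -3.01 and 0.63, so that WT 3 carries much of it), the metalloproteinase inhibitor Timp3 (at least 16.9-fold), Col5a3 (at least 23.1-fold), the extracellular superoxide dismutase Sod3 (at least 8.19-fold, adjusted p = 0.000554), Lurap1l (at least 9.26-fold) and the smooth muscle calponin Cnn1 (at least 14.8-fold). Of the 357 genes that fell, 97 had no KO array above background. Among the dimmest 20% of genes 143 fell and 10 rose, with a median difference of all genes there of -0.39, whereas among the brightest 20% 17 fell and 23 rose, with a median of 0.05.

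**Figure D2:**
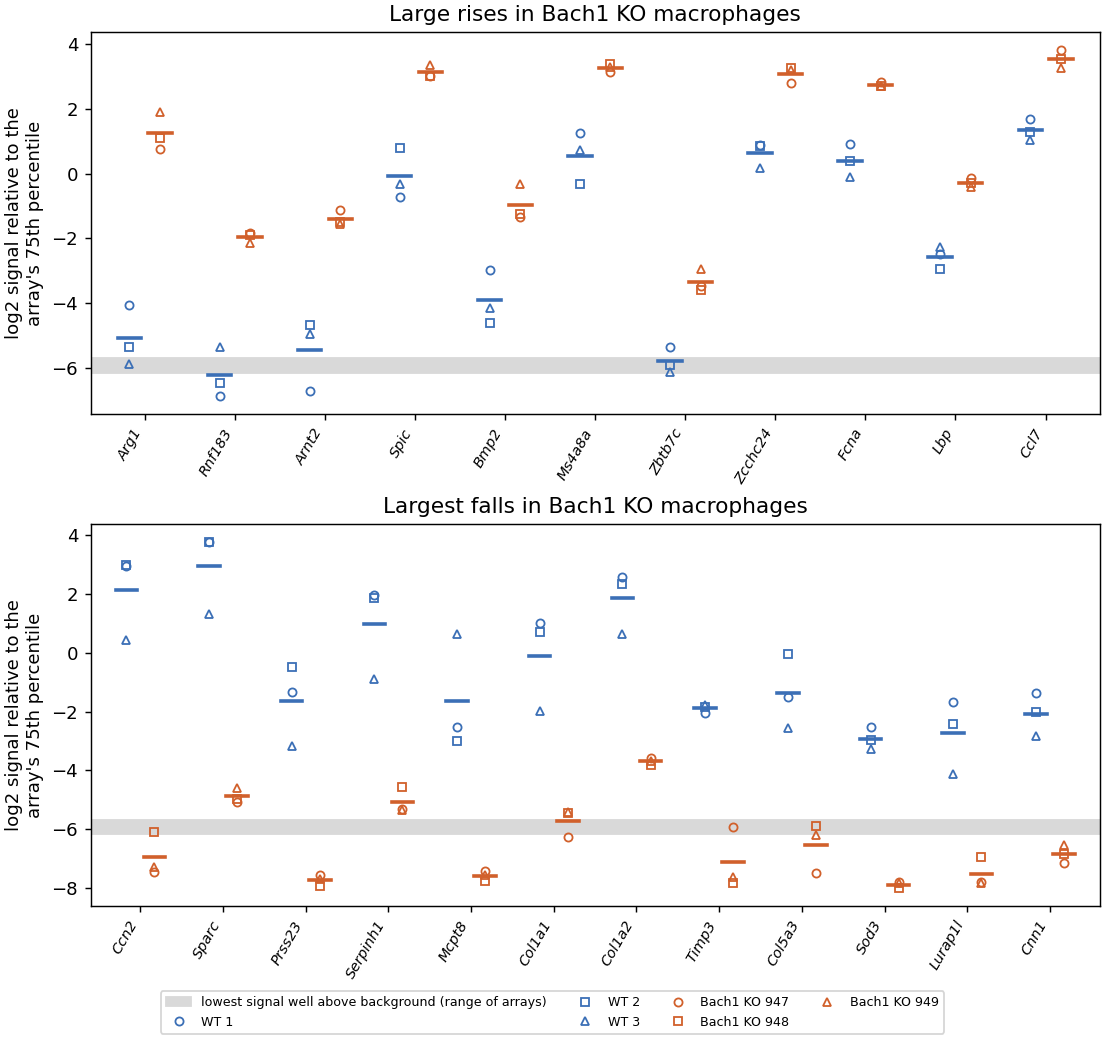
Large rises (top) and the 12 largest falls (bottom) among genes past the threshold (y axis, log2 signal relative to the 75th percentile of the array), with open symbols for single arrays, bars for group means and a grey band for the range over arrays of the lowest signal well above background. Arg1 goes from a WT mean of -5.09 to a KO mean of 1.25, and the KO points of Ccn2, Prss23, Mcpt8 and Sod3 lie at or below the band.

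These counts depended on the arrays and on the slide. With the slide as a block, where KO 947 alone sets the contrast, 84 genes passed, of which 54 were among the 537. Within the slide that holds both genotypes 24 passed. Among the large rises and falls named above, Arg1, Lbp, Ccl7, Ccn2, Sparc, Timp3, Sod3 and Cnn1 still passed with the slide as a block, with differences of 5.85, 2.44, 2.49, -9.60, -8.05, -4.06, -4.88 and -5.09. On KO 947, Ccn2, Timp3, Sod3 and Cnn1 read -7.47, -5.94, -7.80 and -7.17, below that array's lowest level well above background (-5.68). The sizes of their differences are therefore not fixed. Without WT 1, WT 2 or WT 3 the count was 77, 150 or 283, and without KO 947, KO 948 or KO 949 it was 900, 135 or 188. Scaling to the array median put the median difference of all genes at 0.21, against -0.01, and turned the balance of 33.5% higher calls into 62.5%, with 384 genes higher and 230 lower, so the direction of the surplus depends on the scaling. Quantile normalization gave 139 higher and 204 lower, and normexp with quantile normalization 238 and 315.

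Genes of macrophage activation moved in both directions. Among 14 measured genes of the alternative activation list, Arg1 and the mannose receptor Mrc1 (1.07 ± 0.14, adjusted p = 0.0170) rose, whereas Ccl22 (-1.63 ± 0.30, adjusted p = 0.0416) and the PD-1 ligand Pdcd1lg2 (-1.17 ± 0.18, adjusted p = 0.0281) fell. Adjusted over the list alone, 2 rose and 3 fell. Among 18 genes of the classical inflammatory list, Il1a (1.49 ± 0.17, adjusted p = 0.0116) and the monocyte chemoattractant Ccl2 (1.21 ± 0.14, adjusted p = 0.0114) rose, and the interferon-inducible chemokine Cxcl10 (-2.23 ± 0.36, adjusted p = 0.0312) and the costimulatory receptor Cd40 (-2.04 ± 0.41, adjusted p = 0.0499) fell (4 rises and 4 falls adjusted over the list alone). Neither list was shifted as a whole (camera adjusted p = 0.923 and 0.896), and the alternative activation list had a median of -0.14 with a mean of 0.39. With the slide as a block Arg1 and Il1a still passed, Il1a at 1.75 (adjusted p = 0.0428), and the other 6 did not. Ccl22 passed in 8 of 21 alternatives, and Pdcd1lg2, Cxcl10 and Cd40 in 13, 11 and 7 of 23. These and later counts of alternatives include the authors' table for the genes it holds. All its probes separate the groups and all 46 named genes tested in it passed, so a pass there is no evidence. The scavenger receptor Msr1 was the 1 of 20 lipid handling genes that rose (1.35 ± 0.17, adjusted p = 0.0149, and 1.62 with the slide as a block). Among 34 antioxidant and glutathione genes Gstm2 rose (0.78 ± 0.14, adjusted p = 0.0424). Among 18 genes of the amino acid and endoplasmic reticulum stress list Pdia4 rose (1.21 ± 0.23, adjusted p = 0.0442). Ltn1, which lies close to Bach1 on its chromosome, rose by 0.76 ± 0.13 (adjusted p = 0.0387) and was the 1 of 15 measured neighbours in that list to pass. With the slide as a block Gstm2 (0.85, adjusted p = 0.122), Pdia4 (1.56, adjusted p = 0.0702) and Ltn1 (0.79, adjusted p = 0.117) no longer passed. Over 23 alternatives they passed in 9, 10 and 10. Each of these 4 lists had the same number of calls adjusted over the list alone.

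Cell cycle genes passed camera with a preset correlation (adjusted p = 1.74e-05, and 0.00174 with the slide as a block) but not with an estimated one (adjusted p = 0.338). All 23 measured members were higher in KO, by a median of 0.37 (0.58 with scaling to the array median), and with the slide as a block 21 were, by a median of 0.42. No member passed the gene test with limma (8 had an unadjusted p under 0.05, and 2 passed adjusted over the list alone). Mcm5, a subunit of the replicative helicase, differed by 0.76 (adjusted p = 0.0735) and the mitotic kinase Cdk1 by 0.67 (adjusted p = 0.220). With the slide as a block they differed by 0.99 and 0.22. The cholesterol synthesis list missed the threshold (median 0.21, camera adjusted p = 0.0524) and passed with the slide as a block (0.33, adjusted p = 0.0230) but not with an estimated correlation (adjusted p = 0.676), with Srebf2 at 0.73 and Msmo1 at 0.49. No gene passed in the lists of glycolysis (18 measured; Slc16a3 0.83 and Pfkp -0.62, but -0.66 and -0.01 with the slide as a block), the mitochondrial respiratory chain (19; Cox15 0.42, Cox5a -0.16), lysosome and autophagy (22; Lamp2 0.44, Ulk1 -0.35), hypoxia response (12; Ankrd37 0.88, P4ha1 0.85), ferroptosis (14; Hspb1 -3.10, Tfrc -0.97), heat shock (9; Hspb1 and Hspa1a, -0.79), type I interferon response (18; Ifit3 -1.61, Ifi44 -1.43), CNC and small Maf factors (9; Nfe2l1 -0.82, Bach2 0.69 and -0.59 with the slide as a block) or reference genes (12; Ywhaz 0.36, Hprt 0.24, median 0.01). With the slide as a block Cox15 was at 0.05 and Cox5a at -0.21, Hspb1 at -2.88 and Tfrc at -0.48, and Ifit3 at -0.88 and Ifi44 at -0.86. The ferroptosis and heat shock lists had medians of 0.07 and 0.07 with means of -0.16 and -0.31. Adjusted over the list alone, 4 hypoxia genes were higher and 2 heat shock genes lower. In the 15 lists without a call, marker lists included, 22 of 217 members were higher and 14 lower at an unadjusted p under 0.05. Of all 15736 genes 3214 had such a p in the same limma test. The 15 lists were picked for having no call, so this comparison cannot show whether they hold a surplus.

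Markers listed for several cell types other than macrophages were lower in the KO cultures. The dendritic cell list shares Ccl22 with the alternative activation list. Whether its falls reflect fewer such cells or lower expression in macrophages was not tested. Of the dendritic cell markers 6 of 17 fell and all 17 were lower (16 with the slide as a block), with a median of -0.68 (camera adjusted p = 1.91e-08, and 0.241 with an estimated correlation; with the slide as a block -0.67 and 1.68e-05). Ccr7, the receptor that guides dendritic cells to lymph nodes, fell (-2.60 ± 0.24, adjusted p = 0.0093), as did Cd83 (-1.99 ± 0.20), the class II transactivator Ciita (-1.89 ± 0.19) and Ccl22 (-1.63 ± 0.30). Of these 4 Ciita alone passed with the slide as a block (-2.14, adjusted p = 0.0404). Stromal markers had the lowest median, -3.21 (-2.94 with 1 gene at its bound, -2.13 with normexp and quantile normalization, -3.94 with the slide as a block), and 3 of 10 fell, Sparc, Col1a1 and Col1a2 (camera adjusted p = 1.68e-06, 0.279 with an estimated correlation and 3.95e-05 with the slide as a block). Of the eosinophil, mast cell and basophil markers 3 of 12 fell and all 12 were lower, with a median of -2.01, of -1.13 without KO 949 and of -1.30 with normexp and quantile normalization (camera adjusted p = 2.32e-05, and 0.447 with an estimated correlation). With the slide as a block the median was -1.28 (camera adjusted p = 0.0134), and Cpa3 (0.92) and Mcpt4 (0.11) were higher in KO. The 3 that fell were Mcpt8, Prss34 (-3.49 ± 0.63, adjusted p = 0.0406) and the stem cell factor receptor Kit (-3.23 ± 0.59, adjusted p = 0.0420, 2 of 3 KO arrays above background). None of the 3 passed with the slide as a block (adjusted p = 0.131, 0.177 and 0.102), and they passed in 15 of 21, 10 of 22 and 7 of 20 alternatives. Granulocyte markers had a median of -0.62 (-0.40 with scaling to the array median) and 1 of 16 fell, the calprotectin subunit S100a9 (-1.01 ± 0.15, adjusted p = 0.0256; camera adjusted p = 0.00405, 0.279 with an estimated correlation and 0.0124 with the slide as a block). S100a9 itself did not pass with the slide as a block (-1.18, adjusted p = 0.0660), and it passed in 11 of 22 alternatives. Adjusted over each list alone, 9 dendritic cell, 8 stromal, 6 eosinophil, mast cell and basophil and 6 granulocyte genes fell. Without KO 947 the granulocyte list did not pass (adjusted p = 0.0659).

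The macrophage markers were not shifted (19 measured, median 0.08 and -0.04 with the slide as a block, camera adjusted p = 0.675), although Msr1 and Mrc1 rose. Among alveolar macrophage markers, the scavenger receptor Marco rose (1.89 ± 0.30, adjusted p = 0.0295; 1 of 14). Among monocyte markers 2 of 10 rose, including fibronectin (Fn1, 1.78 ± 0.29, adjusted p = 0.0318). Their list had a median of -0.24 and a mean of 0.10 and was not shifted (camera adjusted p = 0.956). The carbonic anhydrase gene Car2 fell (-1.81 ± 0.34, adjusted p = 0.0436) among 8 erythroid markers. With the slide as a block Marco (1.80, adjusted p = 0.147), Fn1 (1.65, adjusted p = 0.153) and Car2 (-1.30, adjusted p = 0.201) no longer passed, and none of the 3 passed with it as a random block. They passed in 14, 13 and 10 of 23 alternatives. Lymphoid (13 measured; Cd3g -2.38, Ccl5 -2.09), megakaryocyte (5; Gp6 -0.71, Ppbp -0.36) and osteoclast markers (10; Itgb3 -0.64, Dcstamp -0.60) had no gene past the threshold, and the osteoclast list had a median of 0.02 with a mean of -0.07 (median -0.13 with the slide as a block). With the slide as a block Cd3g was at -0.64, Ccl5 at -2.54, Gp6 at -0.25 and Ppbp at -0.97. Adjusted over the list alone, 2 macrophage genes rose and 1 fell, 1 alveolar macrophage gene rose and 2 fell, 2 monocyte genes rose and 1 erythroid gene fell.

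**Figure D3:**
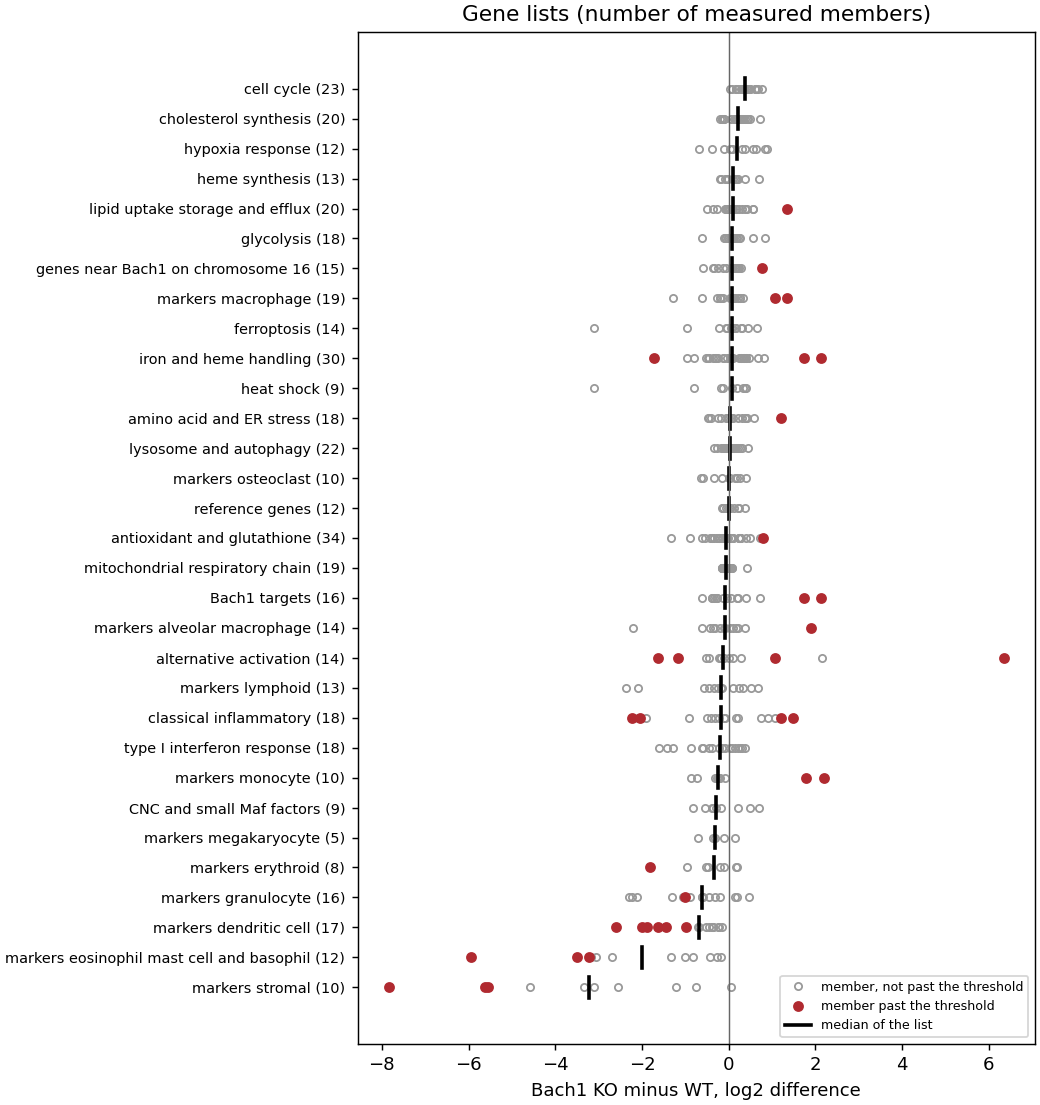
Log2 differences, KO minus WT (x axis), of the measured members of each of the 31 gene lists tested (y axis, number of members in brackets), with filled red points for genes past the threshold, open grey points for others and a black bar at the median. Stromal markers have the lowest median, -3.21, and cell cycle genes the highest, 0.37.

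The labelled sex of each mouse allowed a check of the labels and a comparison of females with males. The Y-linked gene Eif2s3y read 3.81, 4.09, 3.97 and 3.57 on the arrays labelled male (WT 1, WT 2, KO 947 and KO 948) and 3.56 on WT 3, the WT array labelled female. It was not above background on KO 949, the KO array labelled female (-7.75). Ddx3y, also Y-linked, read 0.54 to 1.18 on the arrays labelled male, 0.92 on WT 3 and -7.61 on KO 949. Of 2 Xist probes, neither was above background on WT 3 and both were on KO 949 (-2.42 and -3.57), and 1 was on KO 948 (-3.15) and the other on WT 1 (-3.88), both labelled male. Kdm5d was well above background on 5 arrays, KO 949 among them, and differed by 0.06 between arrays labelled female and male, and Uty was well above it on none. The female minus male difference with genotype as covariate was -5.96 ± 2.28 for Eif2s3y and -4.22 ± 1.86 for Ddx3y, and neither passed (adjusted p = 1.00 for both). Syce1, a synaptonemal complex gene, was the 1 gene that differed between arrays labelled female and male (-6.48 ± 0.37, adjusted p = 0.0361; 447 genes had an unadjusted p under 0.05). Syce1 read -8.03 on WT 3 and -7.83 on KO 949, below the lowest level well above background, so the size of its difference is not fixed. The interaction of genotype with labelled sex passed for 4 genes, with each call resting on the single arrays WT 3 and KO 949. They were Eif2s3y (interaction -11.13 ± 0.43, adjusted p = 0.00697), Ddx3y (-9.06 ± 0.36, adjusted p = 0.00697), Steap1 (8.82 ± 0.46, adjusted p = 0.0196) and Slc8a1 (6.68 ± 0.42, adjusted p = 0.0406), in a fit with 2 residual degrees of freedom and 1 array labelled female per genotype. Eif2s3y and Ddx3y on KO 949, Steap1 on WT 3, KO 947 and KO 948, and Slc8a1 on WT 3 lay below the lowest level well above background. The sizes of these interactions are therefore not fixed. Syce1, Steap1 and Slc8a1 are named because so few genes passed, after their values were seen. As the Y-linked levels of WT 3 go against its label, every direction by sex holds for the labels only. If WT 3 is male, sex is not balanced between the genotypes. On the arrays labelled male, which leave out WT 3 and KO 949, 182 genes differed by genotype.

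**Figure D4:**
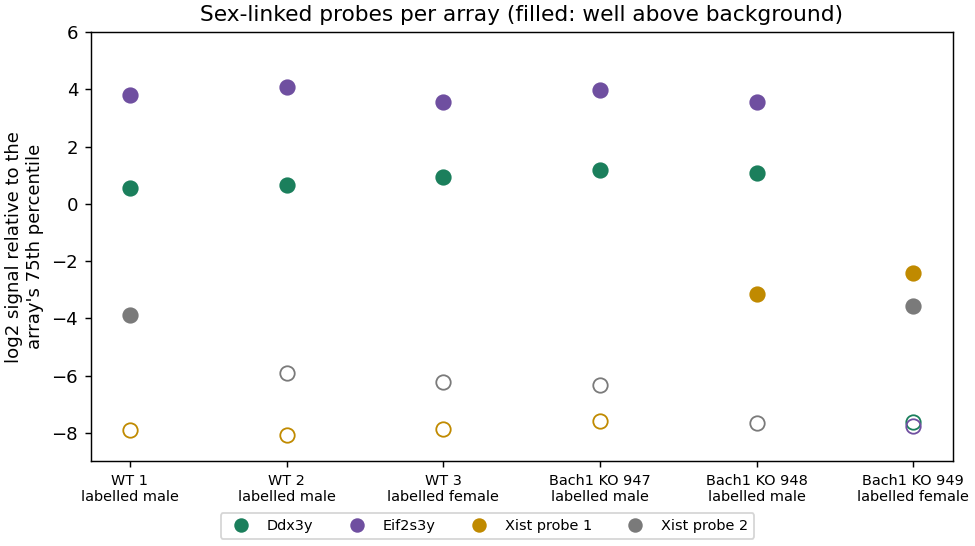
Levels of the Y-linked genes Eif2s3y and Ddx3y and of 2 Xist probes on each of the 6 arrays (y axis, log2 signal relative to the 75th percentile of the array), with filled points for probes well above background. On WT 3, labelled female, Eif2s3y lies at 3.56, and on KO 949, labelled female, at -7.75.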

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

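The tests of the Y-linked levels were chosen after those levels had been seen, as were the tests of the slide that holds the other KO arrays and of variation among WT cultures for the stromal genes. The other tests were set before their results were seen.

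A test of the interaction of genotype with labelled sex flagged 4 genes, each on the single arrays WT 3 and KO 949. They were Eif2s3y (-11.13), Ddx3y (-9.06), Steap1 (8.82) and Slc8a1 (6.68). Each size rests in part on arrays below the lowest level well above background, so it is not fixed. A wrong sex label for WT mouse 3 may account for the first 2, since Eif2s3y read 3.56 on that array, close to the arrays labelled male (3.57 to 4.09). Male RNA mixed into a female sample stays open too. On that array 0 of 2 Xist probes were well above background while both were on KO 949, but 1 was on KO 948 (-3.15) and the other on WT 1 (-3.88), both labelled male, so these probes do not separate the labelled sexes. The Y-linked levels go against the label of WT 3 but not that of KO 949, where Eif2s3y (-7.75) and Ddx3y (-7.61) were not above background. Whether the label of WT 3 is wrong, and whether the mouse or only the record differs, stays open, and no biological explanation was tested. Steap1 was near background on WT 3, KO 947 and KO 948 (-7.97, -7.69 and -7.86) and higher on WT 1, WT 2 and KO 949 (-1.56, -2.10 and -5.09), and Slc8a1 was lowest on WT 3 (-7.35).

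Among the probes with no gene symbol, which the comparisons of genes leave out, 113 of 17616 tested differed between genotypes (21 higher and 92 lower in KO). They were flagged as a signal outside the named genes.

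Stromal genes were low in all 3 KO cultures. The slide is argued against, since KO 947, on the slide of the WT arrays, differed from them by a median of -3.94 over the stromal markers. A lower sensitivity of the KO arrays is argued against too, but only for stromal genes near the markers' median WT level of -1.25. There 2472 other genes had a median difference of -0.00771. For dimmer stromal genes, such as Cxcl12 (WT mean -3.60) and Bgn (-4.21), lower sensitivity stays open. The dimmest group of genes by brightness had a median difference of -0.39, with 143 falls and 10 rises. Fewer stromal cells in the KO cultures remain a possible explanation, as a second stromal list written before its values were seen had a median of -1.62, with 15 of 18 genes lower and 2 past the threshold, although Lepr (0.05) did not move and Dcn (-1.21) did not separate the genotypes. In the second list Col4a1, Col4a2, Thbs2 and Igfbp7 (WT means -4.01, -4.34, -4.34 and -2.67) had no KO array well above background. The sizes of their falls are not fixed, and lower sensitivity stays open for such dim genes. Stromal content may also vary between cultures of 1 genotype, since over both lists WT 3 lay below WT 1 and WT 2 by a median of -1.38, with 22 of 28 genes lower, while the genes called at least 2-fold lower, picked in part for their small spread, gave 0.03. An effect of Bach1 on such cells or on their genes in macrophages stays open, untested.

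With the slide in the model 84 genes were called in place of 537. Of 900 genes called without KO 947, that array lay on the same side of the WT mean in 85.4%, above the 71.2% (highest 74.2%) of 100 simulations of unchanged genes sharing the WT arrays but under the 90% set in advance. A slide effect and a genotype effect therefore cannot be told apart for part of these genes, since 1 KO array shares the slide of the WT arrays. The block raised the standard errors of the 537 genes 1.33 times at the median, but the count within the shared slide, 24, was lower again, so fewer arrays behind the contrast could not be separated from a slide effect by these counts.

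The real split of the 6 arrays called 537 genes, and the highest of the other splits into 3 and 3 called 0. The 10 splits are too few for a share under 0.05, since 1 of 10 is the smallest they can give.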

How the results depend on the processing

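The test without the marker lists of other cell types was chosen after seeing the data. The Bach1 difference did not pass under any alternative run (-0.98 to -0.31), and no sign was reversed in a result past the threshold. For the 537 genes, whose groups did not overlap, leaving out arrays or using the slide as a fixed block could not reverse a sign. Causes were not tested except where the setting itself tests fewer genes or arrays. Against 537 genes changed (419 at least 2-fold), there were 343 (268) with quantile normalization, 275 (266) with no filter on dim probes, 84 (84) with the slide as a fixed block, 255 (249) with it as a random block, 24 (24) within the slide that holds both genotypes, where the lone KO array is assumed to vary like the WT arrays, 182 (182) on arrays labelled male only and 1747 (925) with array weights. There were 305 with labelled sex as a covariate, which may be wrong for WT 3. Trend and robust gave 810, and an adjusted p under 0.1 gave 1151. The authors' table, which holds probes that separate the groups, gave 1519 of 1606 genes. Leaving out 1 array gave 77 to 900 (77 to 686 at least 2-fold). The other settings stayed within 1.5 times. Of 5 lists shifted, 0 passed with an estimated correlation and 1 without the marker lists, which removes the other 4 by construction, and 4 passed with fry, which tests each list against no change and not against other genes, where the eosinophil, mast cell and basophil list did not (adjusted p = 0.0760). The 1 gene differing by sex became 0 with normexp, with no filter and with a filter on all 6 arrays, and the 4 interaction genes became 2, 2 and 0. Of 48 named genes past the threshold, 11 still passed with the slide as a fixed block and 35 as a random block, 25 on arrays labelled male only, and 20, 26 and 36 without WT 1, 2 and 3 and 44, 25 and 30 without KO 947, 948 and 949. Signal over background limits the lowest levels, since 97 genes that fell had no KO array above background.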

Other observations

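The test of neighbours of Bach1 and that of red pulp macrophage genes were set before their results were seen, but the lists were written after the rise of Spic and Ltn1 had been noticed.

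WT 2 stood apart from WT 1 and WT 3 in Bach1 target genes. It had the highest WT level in 13 of 16 targets (81.2%), by a median of 0.58 over the other WT arrays, against 30.7% of all genes. The same array was highest in 9 of 12 hypoxia response genes, 6 of 9 CNC and small Maf factors, 21 of 34 antioxidant and glutathione genes and in 0 of 18 type I interferon response genes, where its median lay at -0.69. Without WT 2 the Bach1 target list had a median of 0.02, and its camera adjusted p was 0.0897. As WT 2 is the highest WT array in most of these targets, leaving it out moves the list upward by construction. This value is therefore no evidence of a hidden rise. Without any other single array the median lay between -0.24 and -0.03 and the camera adjusted p between 0.622 and 0.993.

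The KO arrays differed widely among themselves in 3 of the 12 eosinophil, mast cell and basophil genes. Mcpt8 had an SD of 0.16 there, but it was well above background on no KO array. Its small spread therefore does not show that the KO cultures agreed. Epx had a mean of -3.15 ± 3.58 in KO against -0.09 ± 1.23 in WT, Prg2 2.34 ± 2.55 against 5.02 ± 0.72 and Cpa3 -2.97 ± 3.58 against 0.21 ± 0.92, so none of the 3 passed (adjusted p = 0.361, 0.262 and 0.334). These 3 genes were named after their values were seen. Other genes past the threshold were the vascular adhesion gene Vcam1, which fell by 2.56 on the log2 scale, and the endothelial receptor Robo4, which fell by 4.01 with 1 of 3 KO arrays above background, chosen after their values were seen. Neither passed with the slide as a block (adjusted p = 0.0583 and 0.162). An endothelial list had a median of -0.30, with 1 of 6 genes past the threshold.

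Since Spic, Hmox1 and Slc40a1 rose together, a hypothesis was that the KO cells take up a red pulp macrophage programme. The other 8 measured genes of that programme had a median difference of -0.15, with 3 higher and 5 lower, so they did not rise as a set. The 1 that passed, Vcam1, fell. Vcam1 is also a vascular adhesion gene, and its fall cannot be assigned to macrophages in cultures where stromal markers fell too. Blvrb and Slc48a1 among the 8 are listed Bach1 targets as well, so whether part of the programme is taken up stays open. The hypothesis that strain-derived sequence around the targeted gene changed nearby genes was tested on the 20 nearest measured genes on each side of Bach1. Of these 40 genes 1 was called (Ltn1), against 1.37 expected (one-sided exact hypergeometric p = 0.751), so there was no surplus of calls. Modest changes could be missed, since the fit called 46.3% of genes changed 2-fold in the simulation. A wider effect of that size and Ltn1 itself therefore stay open.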
